A study of Mus musculus with 4 samples.

How the data were processed

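Gene expression was measured in 2 populations of mouse bone marrow cells on Affymetrix whole-genome mouse arrays, 1 array per group. LSK cells carry no mature lineage markers and express c-Kit and Sca-1, and this fraction holds the hematopoietic stem cells and multipotent progenitors. MP cells are the lineage-negative, c-Kit-positive and Sca-1-negative myeloid progenitors. Per the labels, mice carried floxed alleles of Smo, which encodes the hedgehog signal transducer Smoothened, with or without the Mx1-Cre transgene, whose promoter responds to interferon. All mice received 3 injections of the interferon inducer polyI:C at 20 ug per g, and marrow was taken 6 weeks later. Marrow of 4 mice per genotype, males and females mixed, was pooled before sorting. Each genotype is thus 1 pool, from which both populations were sorted, and 20 ng of total RNA per sample went through 2 rounds of amplification.

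The authors deposited 1 table of intensity values for the 4 arrays, made with RMA (background correction, quantile normalization and probe set summary for Affymetrix arrays) per the submitters' processing notes; the version of the software is not given in the sources used here. RMA gives values on a log2 scale, but the deposited values run from 12.3 to 44290.5, so they were read as intensities on a linear scale and log2 was taken without a pseudocount. The medians of the 4 arrays lay between 149.1 and 150.3. RMA draws the arrays to 1 common distribution before the probe set summary, so a change shared by most genes may have been removed. The deposited values were not fully equal, with upper quartiles from 543.1 in Smo-deficient MP to 609.7 in Smo-deficient LSK. Scanner files were not used here.

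The table held 45101 probe sets. The 64 control probe sets were set aside for quality checks, which left 45037. Gene names came from the annotation table of the array platform: 34945 probe sets had 1 gene, 932 had several and 9160 were not named there. Entrez identifiers of 34754 probe sets matched a gene of the RefSeq mouse table used here, and none of the symbols had to be updated. The 18193 named genes were each represented by the single-gene probe set with the highest mean over the 4 arrays. Probe sets were kept for counts and tests when their mean over the 4 arrays was above the 50th percentile, a log2 intensity of 7.23, which left 22518 probe sets of 11904 genes.

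With 1 pool per genotype, the differences between genotypes have no replicate check and no p-value was computed for them. Probe sets with a difference of at least 2-fold (1 on the log2 scale) were counted. Single differences were set beside the scaled median absolute deviation of the same difference over probe sets of like mean level, in 20 bins, called the spread below. It describes these arrays and is not a replicate error. LSK was tested against MP with limma's lmFit and eBayes (trend on mean level, two-sided), with the genotype, which is also the pool, as a block. That design has 2 pairs and 1 residual degree of freedom per probe set before moderation. Benjamini-Hochberg adjusted p under 0.05 counted as passing. The block removes the difference between the pools, so the residual is how far LSK minus MP differs between 2 pools of different genotype. A true effect of genotype on that difference is thus counted as noise, and the p-values do not measure the spread between mice of 1 genotype. In simulated data on the same 22518 probe sets, 200 of them were changed. The test recovered 100% of those changed by 1 on the log2 scale and 100% of those changed by 2, with 7 false calls among 207. The simulated noise had 1 size per bin of mean level and no genotype differences, so this is not the recovery on these arrays. There, Ddit4 (1.43) and Iglv1 (1.40) exceeded 2-fold in LSK minus MP by the mean of both pools and did not pass. Their differences were not shared by the pools, with -0.03 in WT and 2.89 in Smo-deficient for Ddit4, and 3.36 and -0.55 for Iglv1. They are thus not examples of shared differences that the test missed.

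There were 19 gene lists and 8 lists of cell type markers, which gave 81 list medians over 3 comparisons (genotype in LSK, genotype in MP, LSK minus MP). Of their 410 symbols, 369 were measured. Each median was given its percentile among 10000 random gene lists of the same size, matched on mean level. List medians used all measured genes, those below the filter included. Genes of a list are not independent, so this percentile describes these arrays and is not a p-value. Chance would put 4.05 of the 81 medians outside the central 95% of random lists, and 35 lay outside. In simulated data on 11904 genes, a list shifted by 0.5 reached percentile 100 and 6.5% of 200 unshifted lists fell outside. The simulated genes varied independently of each other, and the 4.05 rests on the same assumption. Neither shows how often real lists, whose genes vary together, would fall outside. The counts, lists, the fold threshold, the test and the naming rule were chosen before the data were examined. Lists of plasma cell genes and of the interferon-inducible 200 family, and the comparison of list medians between populations, were added afterwards.

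Genes are named by a fixed rule. It takes the 10 genes most raised and the 10 most lowered by genotype in each population, up to 12 genes per direction that are 2-fold in both, and the 12 highest in LSK and in MP among those that passed the test and were 2-fold in both genotypes. It adds hedgehog genes, genes that mark the sort, sex-linked genes, and up to 4 members of each list. The gene for Sca-1, Ly6a, was not analysed here because the probe annotation used does not name it. Alternatives tried were no filter and a filter at the 75th percentile, quantile and cyclic loess normalization of the deposited values, 1 probe set per gene, the mean of all probe sets of a gene, thresholds of 1.5-fold, 3-fold and 4 times the spread, and limma without the block, without the trend or over both populations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.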

Results

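LSK and MP cells were compared between 1 pool of 4 wild-type (WT) mice and 1 pool of 4 mice in which Smo had been deleted by Mx1-Cre, giving 4 arrays in 4 groups of 1. No value below has a replicate of its own group, and the number of arrays limits the precision. The arrays were close to each other, with Pearson correlations across probe sets from 0.980 to 0.994. The 3' to 5' difference of the Actb control probe sets, a sign of RNA integrity and amplification, was 1.55 on the log2 scale in WT LSK, 1.53 in Smo-deficient LSK, 1.34 in WT MP and 1.31 in Smo-deficient MP. For Gapdh it was 1.57, 1.78, 1.59 and 1.60 in the same order, highest in Smo-deficient LSK. Hybridisation spikes of the Smo-deficient MP array lay below those of the WT MP array by a mean log2 difference of -0.33 ± 0.12 (SD over 9 probe sets), while in LSK the difference was 0.08 ± 0.06. Between LSK and MP they differed by 0.08 ± 0.08 in the WT pool and 0.49 ± 0.09 in the Smo-deficient pool. Poly-A spikes, which are added to the RNA before amplification, were higher in LSK than MP by 0.44 ± 0.25 and 0.59 ± 0.18 (SD over 12 probe sets) in these pools.

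The targeted gene was read first, in every sample. On the Smo probe set 1427049_s_at, log2 intensity was 10.81 in WT LSK and 6.13 in Smo-deficient LSK, 25.7-fold lower, and it was 10.40 in WT MP and 6.36 in Smo-deficient MP, 16.5-fold lower. Of the 22518 probe sets past the filter it had the most negative genotype difference in both populations. Both Smo-deficient values lie below the level of the filter on dim probe sets. A second Smo probe set, 1427048_at, was 8.31-fold lower in Smo-deficient LSK and 3.43-fold lower in Smo-deficient MP, with a log2 intensity of 6.96 in Smo-deficient LSK that is also below that level. The exact folds against such dim values depend on the background. One more probe set, 1442215_at, was dim on all arrays, with log2 intensities from 4.39 to 4.70. Where these probe sets lie relative to the deleted part is not given in the sources used here. The lower values on 1427049_s_at and 1427048_at show less Smo signal in the Smo-deficient pool, but not whether they read the deleted part itself. An unchanged value on a probe set outside that part would check nothing.

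The rest of the hedgehog pathway differed little between genotypes. The 26 other measured members of the pathway list had genotype differences from -0.37 (Evc2, a ciliary regulator of Smoothened) to 0.26 (Hhat, which palmitoylates hedgehog ligands) in LSK, and from -0.42 (Ptch1, the hedgehog receptor) to 0.34 (Boc, a co-receptor) in MP. Of these 26 genes, 17 were past the filter. In LSK 25 of the 26 lay within 2 spreads of 0, and in MP all 26 did. Gli1, whose transcription follows pathway activity in many tissues, differed by 0.02 in LSK and 0.17 in MP, and Ptch1, also a target, by 0.09 and -0.42, while another Ptch1 probe set past the filter differed by -0.24 in LSK and -0.00 in MP. The other genes fixed for this comparison, Gli2, Gli3, Sufu, Hhip, Shh, Ihh and Dhh, differed by at most 0.30 in either population on the probe set representing each. Their dimmer probe sets differed by -0.38 (Dhh) to 0.22 (Sufu) in LSK. Gli1, Gli2, Gli3, Hhip, Ihh and Dhh were below the filter on dim probe sets in these cells, so a change in them could have gone undetected. The median of the pathway list was -0.04 in LSK (percentile 45.8 among random lists) and -0.04 in MP (26.7), and that of the hedgehog target list was -0.01 (63.4) and 0.02 (87.9).

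**Figure D1:**
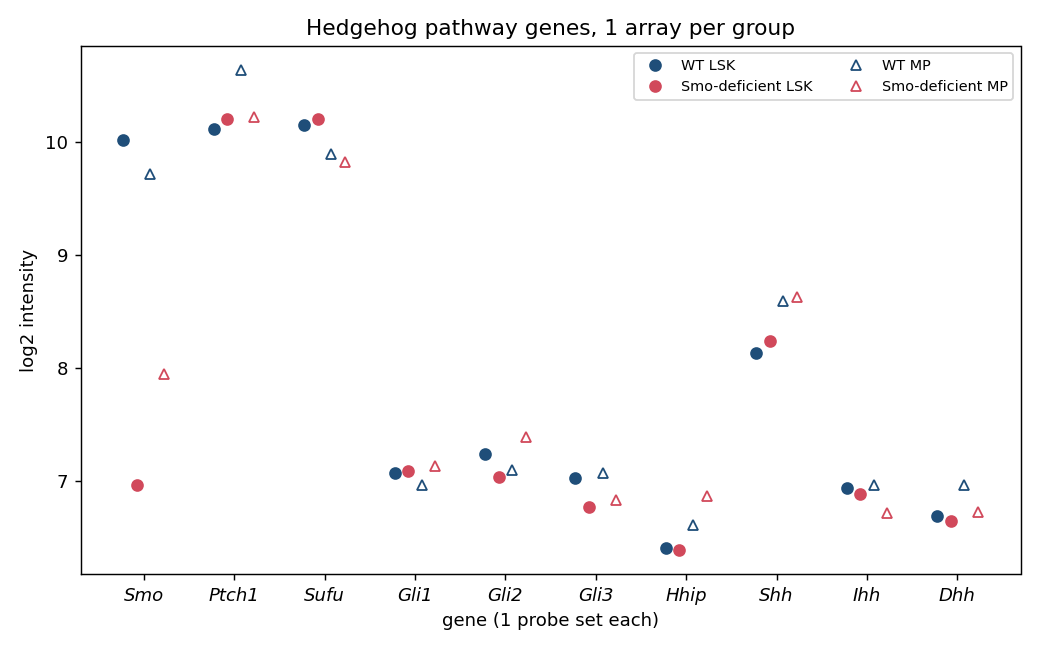
Log2 intensity of 10 hedgehog genes on the 4 arrays, 1 probe set per gene and 1 point per array (circles LSK, triangles MP, blue WT, red Smo-deficient). Smo (probe set 1427048_at) is the gene whose points part by genotype, by -3.05 in LSK and -1.78 in MP; levels of different genes are not comparable with each other.

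Smo-deficient LSK cells had higher levels of lymphoid priming genes and lower levels of erythroid and megakaryocyte genes than WT LSK cells. The lymphoid priming list had a median difference of 1.14, above all 10000 random lists, with 14 of its 15 measured members higher and 8 of them at least 2-fold. Among the 14, Ighm counted as higher at 0.10 on 1427351_s_at, but its other probe sets ranged from -4.41 to 0.55. Among its members past the filter, Dntt (2.15), which adds nucleotides at antigen receptor junctions, and the chromatin organizer Satb1 (1.34) had the largest differences. The recombinase gene Rag1 (1.76) and the chemokine receptor gene Ccr9 (1.27) were below the filter, so the sizes of their differences are uncertain. Over the 12 members past the filter the median was 1.07, with 6 at least 2-fold higher. Granulocyte and monocyte progenitor genes were also higher, all 18 of them, with a median of 0.63 that was above all random lists, led by Fcgr3 (1.27), Irf8 (1.26), Csf1r (1.21) and Gfi1 (1.18). Erythroid genes had a median of -0.26 and megakaryocyte genes one of -0.56, both below all random lists. Of the 19 erythroid genes 8 were higher, among them the anion exchanger gene Slc4a1 (0.80) and the heme synthesis gene Alas2 (0.53). Carbonic anhydrase 1 (Car1) differed by -1.40, sphingosine kinase 1 (Sphk1) by -1.25 and the erythroid transcription factor Gata1 by -0.79. None of the 15 megakaryocyte genes was higher, and the platelet genes Ppbp, Vwf and Gp1bb differed by -1.14, -1.13 and -1.01.

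Several lists of cell type markers were higher in the same Smo-deficient LSK array. The lineage gate is meant to remove mature cells, but not all of these genes mark mature cells. The B cell list holds early B lineage genes such as Vpreb1 and Ebf1, and the dendritic cell list shares Flt3 with lymphoid priming. The neutrophil markers had a median difference of 0.77 (Mmp8 1.25, Mmp9 1.13), macrophage markers 0.63 (Vcam1 0.85, C1qb 0.78) and B cell markers 0.56 (Ms4a1 0.86, Vpreb1 0.75), each above all random lists. The B cell factor Ebf1 was below the filter, and without it the B cell median was 0.51. Mature erythroid markers had a median of 0.40 (percentile 99.97) and dendritic cell markers one of 0.43 (99.99), whereas T and NK cell markers had 0.04 (89.3), mast cell and basophil markers -0.08, and stroma and endothelium markers -0.16 (3.61). Stem cell genes had a median of 0.06 (96.0), with Mn1 at 1.30, the endothelial protein C receptor gene Procr at 1.11 and Slamf1 at -0.51. Proliferation genes had a median of -0.21 (0.02), with cyclin E1 (Ccne1) at -0.62 and Plk1 at -0.51, and genes of quiescence and CDK inhibitors one of 0.17 (99.6).

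In all, 134 probe sets were at least 2-fold higher and 51 at least 2-fold lower in Smo-deficient LSK, 0.822% of those past the filter, but at 3-fold 9 were higher and 14 lower. The genes most lowered, beside Smo, were Iglv1 (-3.22), an immunoglobulin light chain segment, the metallothioneins Mt1 (-1.87) and Mt2 (-1.74), the apoptosis regulator Pawr (-1.86), Ccnb1ip1 (-1.82), which acts in meiotic crossing over, and the collagen gene Col1a2 (-1.76). A second probe set of Mt1 differed by -0.09. The genes most raised, after Dntt, were Mir1931 (1.90), Fcrla (1.84), the B cell coactivator Pou2af1 (1.81), the Y-linked Eif2s3y (1.70), Kdm5d (1.67) and Uty (1.44), Nrp1 (1.45), Dhrs3 (1.45) and Id2 (1.43). Of 113 genes that were 2-fold, 31 had another probe set past the filter, for 29 the others had the same sign, and for 15 they reached 1.5-fold. Csf1r and Nrp1 had other probe sets at 0.49 and 0.53. These differences stand between 1 pool and 1 pool, so genotype, sex makeup and any other difference between the pools are not separated.

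In MP cells the same lists parted by genotype for erythroid and granulocyte and monocyte genes, while megakaryocyte genes did not stand apart. All 18 granulocyte and monocyte progenitor genes were higher in Smo-deficient MP, with a median of 0.61 that was above all random lists, led by Fcgr3 (1.09), Csf1r (1.09) and the glutathione transferase Gstm1 (0.88). Erythroid genes had a median of -0.53, below all random lists, with Sphk1 at -1.04, the blood group gene Ermap at -0.76 and the erythropoietin receptor gene Epor at -0.72. Lymphoid priming genes had a median of 0.53, above all random lists, with Dntt at 1.17, Satb1 at 1.03 and Flt3 at 0.95. The megakaryocyte median was 0.01 (88.2), and proliferation genes had a median of -0.32, below all random lists, with Bub1b at -0.66 and Plk1 at -0.55. Marker medians in MP were 0.20 for neutrophils (99.9), 0.25 for B cells (99.7), 0.00 for macrophages, 0.28 for mast cells and basophils (99.8), 0.16 for dendritic cells (98.8), 0.13 for mature erythroid cells (96.0), 0.01 for T and NK cells and -0.01 for stroma and endothelium.

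In MP 63 probe sets were at least 2-fold higher and 81 at least 2-fold lower in Smo-deficient cells. The direction of this split depended on the normalization and the threshold: it was 86 higher and 63 lower after quantile normalization, 102 and 56 after cyclic loess, and 153 and 117 at 4 times the spread. The genes most lowered were Ccnb1ip1 (-3.50), the stress-induced mTOR inhibitor Ddit4 (-2.45), the receptor kinase gene Mst1r (-1.95), Ammecr1 (-1.93), Pawr (-1.79), the tight junction gene Tjp1 (-1.78) and Smo. The genes most raised were Evl (1.38), Dmkn (1.37), Ms4a4b (1.37), Cryl1 (1.36), Tnfrsf14 (1.36), Gria3 (1.32) and Mndal (1.31), a member of the interferon-inducible 200 family. Another probe set past the filter was present for 29 of the 67 genes that were 2-fold, for 28 of them it had the same sign, and for 14 it reached 1.5-fold. Cryl1 had another probe set at -0.01.

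Several genes parted by genotype in both populations. The 13 genes at least 2-fold higher in Smo-deficient LSK and MP were Mndal, Mir1931, Uty, Dntt, Eif2s3y, Kdm5d, Nrp1, the low-affinity IgG receptor Fcgr3, the macrophage colony-stimulating factor receptor Csf1r, Ly86, H2-Ob, Satb1 and Bcl6. The 9 genes at least 2-fold lower were Ccnb1ip1, Pawr, Smo, Asb17, Mst1r, Myh10, Mt2, Hpn and Sphk1. Xist, expressed from the inactive X chromosome, differed by -0.89 in LSK and -0.47 in MP, against the direction of the Y-linked genes. Among probe sets, 27 were higher and 15 lower in both populations, where independent lists would share 0.375 and 0.183. After quantile normalization these numbers were 34 and 10, after cyclic loess 40 and 11, and at 3-fold 0 and 4. Across the 22518 probe sets, which are not independent replicates, the genotype difference in LSK and that in MP correlated with Pearson's r of 0.51 and Spearman's rho of 0.45. Both populations of a genotype came from the same mice, so this agreement is within 1 pair of pools.

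**Figure D2:**
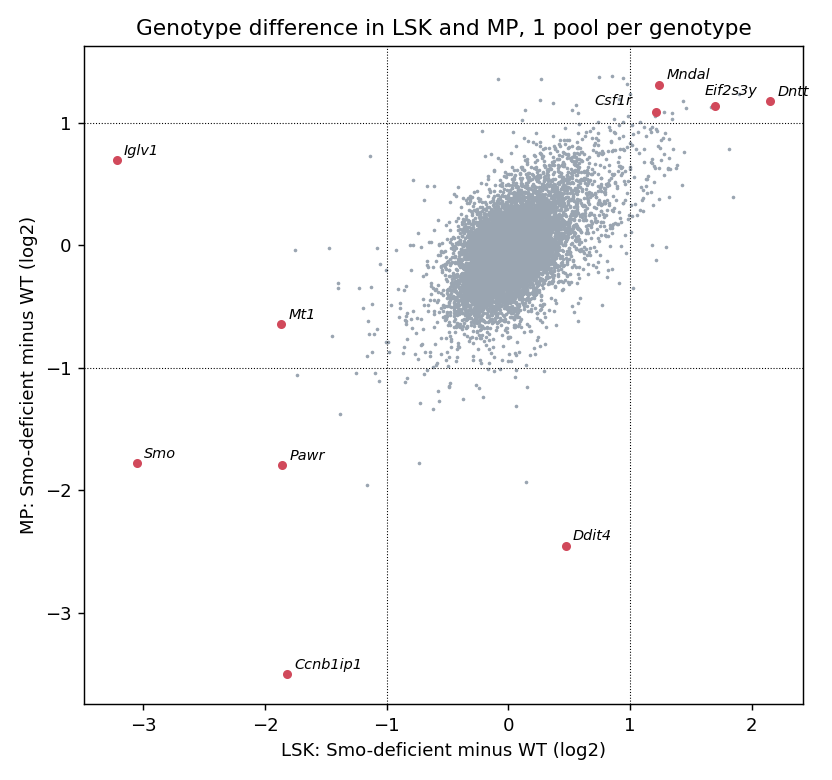
Genotype difference (Smo-deficient minus WT, log2 intensity) in LSK on the x axis and in MP on the y axis, 1 point per gene past the filter, with dotted lines at 2-fold and selected named genes in red. Smo, Pawr and Ccnb1ip1 lie below -1 on both axes, while Iglv1 is at -3.22 in LSK and 0.69 in MP.

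The size of the genotype difference was not the same in both populations for every list. The lymphoid priming genes had a median of 0.52 for the difference in LSK minus that in MP, above all random lists, and the megakaryocyte genes one of -0.51, below all. For the erythroid genes it was 0.31, above all random lists, and for the granulocyte and monocyte progenitor genes -0.01 (percentile 6.16). Hedgehog targets were at -0.16 (0.16), while neutrophil markers were at 0.58 and macrophage markers at 0.51, both above all random lists. A difference of differences of at least 2-fold was seen for 137 probe sets, 102 of them with a positive sign. With 1 array per group it could not be tested.

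**Figure D3:**
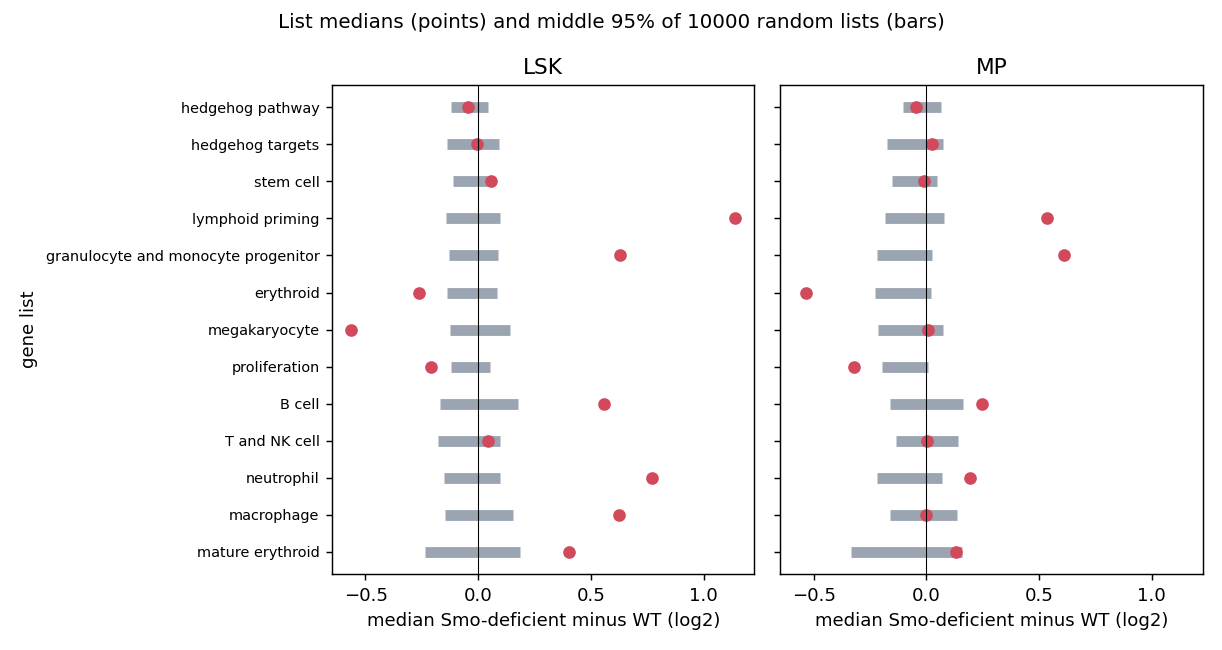
Median genotype difference (Smo-deficient minus WT, log2) of 13 gene lists in LSK and MP as points, with bars for the central 95% of 10000 random lists of the same size and mean level. Lymphoid priming genes are at 1.14 in LSK and 0.53 in MP, and megakaryocyte genes at -0.56 and 0.01.

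LSK cells were set against MP cells to find the genes enriched in the stem cell fraction. Stem cell genes rose in LSK: 19 of 25 tested members passed with limma over all probe sets (19 adjusted over the list alone), 0 fell, and the list median was 1.20, above all random lists. The genes with the largest mean log2 differences included the imprinted growth suppressor Ndn (4.40 ± 0.11 SE, adjusted p = 4.83e-05), Pglyrp2 (3.86), Procr (3.78), Gimap8 (3.71), the transcription factor Mecom (3.57), Vldlr (3.54), Gcnt2 (3.09) and Hlf (2.95). In MP several of these genes were below the level of the filter (Ndn at 6.38 and 6.24, Vldlr at 5.46 and 5.71), so their sizes and order depend on the background there, as do those of genes dim in LSK such as Asb17. The 4 probe sets of Ndn past the filter ranged from 0.99 to 4.68, and another one of Gcnt2 differed by 0.67. Megakaryocyte genes rose in 12 of 15 cases (13 adjusted over the list alone), among them Mmrn1 (2.35), Vwf (1.54) and Rab27b (1.44). Lymphoid priming genes rose in 7 of 12 (8 adjusted over the list alone, with 1 that fell), led by Dntt (2.63), Ltb (2.56) and Gimap6 (2.44).

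Erythroid genes and granulocyte and monocyte progenitor genes were higher in MP. Of 18 tested erythroid genes, 15 fell in LSK and 0 rose (15 and 0 adjusted over the list alone), with Sphk1 at -2.90, Ermap at -1.98 and Rhag at -1.97. Of 18 granulocyte and monocyte progenitor genes, 11 fell and 1 rose, the same numbers as when adjusted over the list alone, with neutrophil elastase (Elane) at -1.64, Ms4a3 at -1.56 and Csf1r at -1.13. The genes highest in MP included Tlcd4 (-3.30), Asb17 (-2.63), Aldh1a7 (-2.59), Hpn (-2.51), Cited4 (-2.48), Atp1b2 (-2.42), Mt2 (-2.41) and Mt1 (-2.24), though the other probe sets of Atp1b2 and Mt1 past the filter differed by -0.49 and -0.33. Of 550 genes 2-fold by the mean of both pools, 213 had another probe set past the filter, for 199 the others had the same sign and for 140 they reached 1.5-fold. All 5 tested mast cell and basophil markers fell in LSK, with the histidine decarboxylase gene Hdc at -1.48, and 0 of 10 neutrophil markers passed. Among genes that mark the sort, Kit differed by 0.22 without passing, Cd34 by 1.06, Flt3 by 1.39 and Mpo, the myeloperoxidase gene, by -0.42.

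Of 22518 probe sets, 5013 passed with limma, 3395 higher and 1618 lower in LSK, and 882 of them were also 2-fold. The share higher in LSK was 67.7%, but 53.7% after quantile normalization of the deposited values (2986 higher, 2570 lower). Without the pool as a block 1058 probe sets passed, and 30 of the 51 calls of named genes were lost, those of Flt3, Cd34, Dntt, Csf1r, Asb17, Mt1, Mt2 and Mpo among them. By 2-fold alone, 662 probe sets were higher and 277 lower in LSK of the WT pool, and 831 and 187 in that of the Smo-deficient pool.

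Most genes enriched in LSK over MP kept that enrichment without Smo. Of 413 genes at least 2-fold higher in WT LSK than WT MP, 316 (76.5%) were 2-fold higher in the Smo-deficient pair too, and 99.5% had the same sign. Necdin (Ndn) was higher in LSK by 4.36 in WT and 4.45 in Smo-deficient cells, Mecom by 3.26 and 3.88, and Hlf by 2.64 and 3.25. Of 168 genes 2-fold higher in WT MP, 99 (58.9%) were 2-fold in the Smo-deficient pair, and 98.8% had the same sign. The order of these shares depended on the pool used to pick the genes. Of genes picked in the Smo-deficient pair, 67.2% of the LSK-enriched and 78.6% of the MP-enriched were 2-fold in WT. The 410 genes 2-fold enriched in LSK by the mean of both pools had a median genotype difference of 0.27 in LSK and 0.22 in MP, both above all random lists, with 20 of them 2-fold higher and 6 lower in Smo-deficient LSK. The 140 genes enriched in MP had medians of -0.30 in LSK and -0.59 in MP, both below all random lists.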

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

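The test on sex-linked genes, the removal of these genes from the second count of neighbouring genes, and the comparison of list medians between populations were chosen after the results they bear on had been seen.

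A pair of probe sets without a gene name in the annotation used here moved in opposite directions in the 2 populations. Probe set 1428719_at had a genotype difference of -3.54 in LSK and 1.70 in MP, and 1428720_s_at one of -3.39 and 2.0. The opposite direction was not tested, since each group is 1 array.

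Smo-deficient LSK cells had more lymphoid priming and less erythroid transcript than WT LSK cells. MP cells carried over into the WT gate would have raised granulocyte and monocyte progenitor genes there, but these were higher in Smo-deficient LSK, at percentile 100. They were also higher in Smo-deficient MP than WT MP, with a median of 0.61. Such a difference between the pools could mask carried-over cells, so these genes cannot decide it. At least 98.5% of the lymphoid priming median remained under quantile and cyclic loess normalization of the deposited values. Those values had already been normalized, so a further normalization could change little. What the first normalization did cannot be judged from it, and normalization as an origin stays undecided. Mature lymphocytes in the Smo-deficient LSK sort, which the lineage gate should remove, cannot be told apart from a change in the progenitors. B cell markers were at percentile 100 but T and NK cell markers at 89.3. Only 4 of the 9 measured T and NK cell markers were past the filter, so a rise in the others could have gone undetected. Of 9 measured B cell markers 8 were higher, Cd79a by 0.60 and Cd79b by 0.56 but Igll1 by only 0.18. Neutrophil (0.77), macrophage (0.63) and mature erythroid (0.40) marker medians were higher in Smo-deficient LSK too. Those of mast cells and basophils (-0.08) and of stroma and endothelium (-0.16) were not. Whether mature myeloid or erythroid cells were in the Smo-deficient LSK sort was not tested. A change caused by loss of Smo, and a chance or sex-related difference between 2 pools of mice, stay open and untested.

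Some immunoglobulin probe sets were far lower in Smo-deficient LSK, and probe sets assigned to 1 gene disagreed. Ighm ranged from -4.41 on 1425324_x_at to 0.55 on 1427329_a_at, Igha differed by -0.58 to -1.0, and Iglv1 was at -3.22 in LSK but 0.69 in MP. B cells in the WT sort would have made B cell markers lower in Smo-deficient LSK, but these were higher, at percentile 100. That does not exclude B cells in the WT sort. Lymphoid priming genes were higher in Smo-deficient LSK as well (median 1.14), and such a rise could mask them. Plasma cells, which the c-Kit gate should remove, could not be excluded: their list had a median of 0.04 at percentile 84.5, inside the range of random lists, and Jchain (0.04) and Xbp1 (0.20) were so bright in WT LSK, at log2 intensities of 10.89 and 12.78, that a small share of such cells would be hidden. Loss of Smo as the origin was not tested separately.

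Of the 22 genes 2-fold in both populations 3 are Y-linked, with a median difference of 1.67 in LSK and 1.14 in MP, and Xist went the other way, so a larger share of cells from male mice is a candidate explanation for these, though the number of males and the cells each mouse gave are not separated. An interferon response is not borne out but stays open: the interferon list was at percentile 97.8 in LSK (82.7 over genes past the filter) and 3.76 in MP, with 0 of its 26 measured genes 2-fold higher in both, and the interferon-inducible 200 family was at 99.8 in LSK (87.9 over the 4 members past the filter) and 99.7 in MP. Chromosome segments of different strain origin, from the mixed background of the mice, would place such genes near each other. Among the 22 genes 3 pairs lay within 5 measured genes, all Y-linked, and 0 remained without these, and among the 181 genes 1.5-fold in both populations that are not Y-linked, the rest of the 22 included, 14 pairs did, against a mean of 8.05 in random sets (percentile 97.35). Some of those pairs belong to the Ms4a gene family, so strain origin, gene families, an interferon response and loss of Smo cannot be told apart here for genes other than the Y-linked ones and Smo.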

How the results depend on the processing

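LSK and MP were paired by pool through the block, and for genotype no paired analysis was possible because each genotype is 1 pool. Counts moved with the thresholds by construction. With no filter, 281 probe sets were 2-fold by genotype in LSK and 251 in the difference between populations. Above the 75th percentile the counts were 86 for genotype in LSK, 72 in MP, 18 shared, 489 and 478 for LSK against MP in the WT and Smo-deficient pools, and 49 for the difference between populations. With 1 probe set per gene they were 113, 67, 22, 581, 596 and 51 in that order, and 2963 for the limma test. At 1.5-fold they were 888, 1123, 312, 2786, 3146 and 942, and at 3-fold 23, 21, 4, 298, 276 and 19. Above 4 times the spread, 349 and 270 probe sets differed by genotype in LSK and MP. A limma fit over both populations, which compares the 2 pools and not the genotypes, called 504. For LSK against MP, 1058 passed without the block, a fit in which the difference between the 2 pools is part of the residual. With the block, 882 passed and were also 2-fold, against 939 and 1018 at 2-fold in the WT and Smo-deficient pools alone. The apoptosis regulators median in MP, 0.10, was -0.054 with the mean of all probe sets, and the cause was not tested.

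Quantile and cyclic loess normalization left each total of 2-fold probe sets and of limma calls within 1.5 times. By direction, higher probe sets in MP went from 63 to 102 under cyclic loess, and lower limma calls from 1618 to 2570 under quantile normalization. Both normalizations left all 152 genotype values of named genes within their spread, whereas the mean of all probe sets moved 61 of them. The median of LSK-enriched genes ranged from 0.20 to 0.32. Dim probe sets, such as those of Gli1 and Hhip, limit what can be seen of the hedgehog targets.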

Other observations

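Other gene groups set LSK cells apart from MP cells. Immediate early genes rose in LSK, 15 of 18 tested members with 2 that fell (16 and 2 adjusted over the list alone) and a list median of 0.66, among them the nuclear receptor Nr4a1 (2.24), Ier3 (1.03) and Egr1 (0.97). These genes respond within minutes to handling as well as to signals, and all cells went through sorting. Interferon response genes rose in 12 of 22 cases and fell in 0 (14 and 0 adjusted over the list alone), with Oasl2 at 2.70, Gbp2 at 2.14 and Iigp1 at 2.09. Genes of quiescence and CDK inhibitors rose in 8 of 12 (10 adjusted over the list alone), with Cdkn1a at 1.04, and 3 of 25 proliferation genes fell, Ccne1 (-1.51), Cdc6 (-0.72) and Plk1 (-0.42), with 0 that rose. Of 13 hedgehog targets tested, 4 rose and 1 fell, with Mycn at 2.21 and Ccnd2 at 0.77, genes that many other signals also drive, and of 18 hedgehog pathway genes 2 rose and 1 fell (0 and 0 adjusted over the list alone). Ribosomal protein genes rose in 1 of 15 cases, oxidative phosphorylation genes fell in 4 of 19, cilium genes rose in 2 of 14, and Notch targets rose in 2 of 8, Wnt targets in 2 of 4, p53 targets in 3 of 10, with 2 that fell (Zmat3 -0.73, Aen -0.50), and apoptosis regulators in 5 of 11, with 1 that fell (Bid -0.52). Of the marker lists not yet described, 4 of 7 dendritic cell markers rose, 2 of 9 macrophage markers fell, 1 of 8 B cell markers rose, 1 of 4 mature erythroid markers rose and 1 fell, and 0 of 4 T and NK cell and 0 of 4 stroma and endothelium markers passed. Of the sex-linked genes, 1 of 4 fell, Eif2s3y (-0.57).

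Other lists were compared by genotype. Medians in LSK and MP were 0.09 and -0.12 for interferon response genes, -0.10 and 0.09 for Notch targets, 0.00 and 0.00 for Wnt targets, 0.13 and -0.07 for p53 targets, 0.01 and 0.10 for apoptosis regulators, -0.04 and 0.05 for immediate early genes, -0.03 and -0.05 for cilium genes, -0.09 and -0.10 for oxidative phosphorylation, and 0.00 and 0.02 for ribosomal proteins. Among these, percentiles outside the central 95% of random lists were 97.8 for interferon response genes in LSK, which was 82.7 over genes past the filter, and 98.2 for apoptosis regulators and 99.5 for immediate early genes in MP. With the mean of all probe sets of a gene, apoptosis regulators in MP were at percentile 50.19, inside that range. The p53 target Trp53inp1 was at 1.38 in LSK and 0.63 in MP. The plasma cell list was at 0.04 and 0.11. The interferon-inducible 200 family, of which Mndal is a member, had a median of 0.25 in LSK (99.8) and 0.25 in MP (99.7), but over the 4 members past the filter these were 0.15 (87.9, inside the range of random lists) and 0.68 (99.98), and Ifi204 differed by -0.78 in LSK and 0.53 in MP. Genes of quiescence and CDK inhibitors were at 0.02 in MP, and stem cell genes at -0.01.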
